A study of Mus musculus with 27 samples.

How the data were processed

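RNA-seq was done on common lymphoid progenitors (CLP), pro-B cells, DN3 thymocytes, splenic natural killer (NK) cells and progenitors of group 2 innate lymphoid cells (ILC2P) from C57BL/6 mice with the genotype Ezh2cKO or control. Per the labels' protocols, cells were sorted on surface markers: CD117, CD135 and CD127 for CLP, CD19, B220 and CD43 for pro-B cells, CD25 without CD117 for DN3 cells, DX5 and NK1.1 for NK cells, and high Sca1 with CD127 for ILC2P. Genes that encode these markers (Kit, Flt3, Il7r, Cd19, Ptprc, Spn, Il2ra, Itga2, Klrb1c, Ly6a) are therefore part of a gate. RNA was extracted on small columns, amplified with an ultra-low-input kit and sequenced on a NextSeq instrument, per the labels' protocols. Each cell type had 3 control libraries; DN3 cells and ILC2P had 3 and the other types 2 Ezh2cKO libraries. Groups and replicate numbers came from the sample titles.

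Per the submitters' processing notes, the tools were Trimmomatic 0.33, TopHat2 2.1.0, HTSeq 0.6.1 and edgeR (version not given), and the genome build was mm10. Per the file headers, the authors deposited a table per cell type with RPKM per library (reads per kilobase of gene width and 1000000 reads), a gene width, log2 fold changes and log2 mean CPM, a likelihood-ratio score, a p-value with an adjusted p-value, and flags of higher and lower genes, which matched an adjusted p below 0.01 with the sign of the fold change. The other columns of the deposited tables gave gene names, positions and width. The tables listed 12692 to 13537 genes each and were normalized separately, so levels set side by side across cell types are not on one scale. The width in these tables is the gene's span with introns, and RPKM times width in kilobases gave CPM that summed to 1000000 in each library, so the deposited RPKM were relative to the reads of the listed genes. Steps of the low values gave whole reads for 100% of the values (tolerance 0.02 reads), and totals of 8.76 to 17.4 per library in units of 1000000 reads. Counting can split reads between similar copies, so values of multigene families (Ly6a, Iigp1, Gbp3, Oas, Klra1 and H2 genes) are uncertain.

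RPKM was recalculated to CPM, and log2(CPM + 1) was tested per cell type with limma 3.58.1 in R 4.3.3 (limma-trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with genes of at least 1 CPM in 2 libraries, which removed no listed gene. This departs from the fallback fixed before the data were examined, which named log2(RPKM + 1) with at least 1 RPKM in 2 libraries. RPKM over the span puts long genes near the pseudocount: the median gene stood at 0.943 to 1.11 RPKM and 18.9 to 22.1 CPM. The change was made before any fit but with the values in view, including that Cdkn2a lies below the RPKM minimum, so the counts of calls, the gene lists, the genes shared by or differing between pro-B and DN3 cells and the calls lost by genes named in the text are also given on RPKM. The design fixed for counts was not run, since the deposited values are RPKM. The planned tests of a shared and of a differing genotype effect in a joint model of all cell types were not run across the separate tables. The difference of the log2 fold changes over their combined standard error replaced the latter and was chosen after the tables were seen. A fit of all 27 libraries was run only as an alternative for the calls within each cell type. Overlaps were tested with Fisher's exact test. With 3 against 2 or 3 libraries, an exact permutation test of a single gene cannot go below 0.1.

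The steps were checked on simulated data with 200 changed genes per cell type. All genes of a simulated cell type had the same dispersion, taken from the spread of its higher genes, and no library effects were added. This dispersion was the median over genes of variance over squared mean within groups of 2 or 3 libraries, averaged over both genotypes. In such small groups that median lies below the mean, so the simulated spread was likely too small and recovery too high. In ILC2P the spread took in the library labelled Ezh2cKO replicate 3, which stood apart and can lower recovery. Changed genes had a mean of at least 5 CPM, so the recovery of lower genes was not tested. Limma-trend recovered, of 100 genes changed 2-fold and 100 changed 4-fold, 98 and 100 in pro-B cells, 100 and 100 in DN3 cells, 47 and 100 in CLP, 5 and 72 in ILC2P and 13 and 89 in NK cells, and called 11, 7, 6, 4 and 3 unchanged genes; without changed genes it called 0. The test of a difference between pro-B and DN3 cells recovered 194 of 194 genes differing at least 4-fold and called 14 without a difference, among 12571 genes.

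Before the data were examined, 27 gene lists were fixed: PRC2 subunits, CDK inhibitors, p53 targets, proliferation, apoptosis regulators, Hox genes, developmental transcription factors, fetal haematopoietic and imprinted growth genes, lymphoid progenitor, B lineage, T lineage, antigen receptor response, ILC2, NK and polarity genes, interferon-stimulated, immediate early and mitochondrially encoded genes, sex-linked genes, and markers of myeloid, erythroid, megakaryocyte, basophil, mature B and plasma, mature T, dendritic and stromal cells. Some genes stand in several lists. Sets were tested with camera (preset correlation 0.01) and again with an estimated correlation, with which no set passed in any of the 5 cell types. That loss need not reflect correlation alone. For DN3 CDK inhibitors it was estimated at 0.002, below the preset, yet the unadjusted camera p rose from 0.000154 to 0.0179. The planned fry test asks if a set changes in 1 direction, without comparing it with other genes. By fry, sets passed in pro-B and DN3 cells only, as given there. Named genes followed a rule fixed at the same time: Ezh2, Ezh1 and Cdkn2a; the 8 higher and 8 lower called genes with the largest log2 fold change, at least 5 CPM in the higher genotype and no overlap between genotypes, leaving out predicted genes, small RNA and antigen receptor segments; up to 4 called members per list; up to 10 genes called in the same direction in most cell types; and up to 8 with the smallest p for a differing effect. The order of the shared genes, by their largest adjusted p over the cell types, was set later. Igkc, Igj, Cd3e, Cd3d, Gata3, Flt3 and the B lineage genes given per library were chosen after their values were seen.

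Same-numbered DN3 libraries deviated together (correlations of deviations from the group means 0.47, 0.37 and 0.21), as far as the data show, since the labels tie no animals or days to the numbers. The number 1 DN3 libraries of both genotypes also held high Xist, and same-numbered libraries of the other cell types shared their pattern of Xist and Y-linked transcripts too (in NK cells by library code). In CLP, ILC2P and NK cells the number 3 libraries held both Xist (324 to 1450 CPM) and Y-linked transcripts (81 to 171 CPM). Blocked values are therefore given beside DN3 results where the block changed a call or moved a count of calls by over 1.5 times. Alternatives were RPKM (for lists, overlap and differences added after the results were seen), median-ratio scaling (in DN3 cells also with the block), limma-voom on the recovered reads, a stricter filter of 10 reads, a pseudocount of 0.1, a 2-fold minimum, the replicate block, a sex covariate, all 27 libraries in one fit and each library left out in turn. Ratios of genes with 1 to 3 reads in a group have 95% counting intervals, and the floor of a group without reads is 3 reads; both cover counting error only. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.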

Results

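RNA was sequenced from 5 lymphoid cell populations sorted from mice designed to lose the histone methyltransferase EZH2 in lymphocytes and from control mice. The first genotype, Ezh2cKO, carried floxed alleles of Ezh2 and a Cre recombinase expressed from the Il7ra locus, which is active from early lymphoid progenitors on. The controls carried the same Cre with an unmodified Ezh2. Common lymphoid progenitors (CLP) and pro-B cells came from bone marrow. DN3 cells, the thymocyte stage at which the T cell receptor beta chain is tested, came from thymus, natural killer (NK) cells came from spleen, and progenitors of group 2 innate lymphoid cells (ILC2P) made up the fifth population. Pro-B cells, CLP and NK cells had 3 control and 2 Ezh2cKO libraries each, and DN3 cells and ILC2P had 3 of each genotype, which gave 27 libraries in all. The reads of the listed genes, recovered from the deposited values, came, in units of 1000000 reads per library, to 15.6 to 17.4 in pro-B cells, 13.5 to 16.2 in DN3 cells, 10.6 to 14.6 in CLP, 12 to 13.5 in ILC2P and 8.76 to 13.1 in NK cells. Mitochondrial ribosomal RNA took 8.37% to 30.5% of them. The labels describe the samples of a genotype as independent. The comparison in each cell type asked how transcript levels differed between Ezh2cKO and control cells. Levels are given in CPM (counts per 1000000 reads of the listed genes) as mean ± SD, with 3 control libraries and the number of Ezh2cKO libraries stated above. Log2 fold changes are Ezh2cKO minus control on the log2(CPM + 1) scale, which understates the change of low genes.

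Ezh2 itself (chromosome 6, 47530274 to 47595341, mm10) was lower in pro-B cells, at 747 ± 75.3 CPM (SD, n = 3) in controls and 452 ± 14.8 CPM (n = 2) in Ezh2cKO, a log2 fold change of -0.72 (SE 0.21) with a limma adjusted p of 0.047. That call was lost when any of the 5 libraries was left out, and on the deposited RPKM scale its adjusted p was 0.128. In DN3 cells Ezh2 stood at 345 ± 2.8 CPM in controls and 303 ± 57.2 CPM in Ezh2cKO (adjusted p = 0.497). The means were 346 and 276 CPM in CLP and 106 and 85.4 CPM in NK cells, where the difference did not pass the test either. In ILC2P the Ezh2cKO libraries held 132, 157 and 711 CPM against 123 ± 16.3 CPM in controls. The values count reads over the whole gene, including exons that a floxed allele keeps after recombination, so they are a weak check of the deletion. How complete recombination was in each population, CLP included, is therefore not known from these data. Ezh1, the paralog of Ezh2, did not pass the test in any of the 5 cell types. In DN3 cells, where Ezh1 fell from 44.2 to 33.3 CPM on average, it passed with the replicate number as a block (adjusted p = 0.0192), with median-ratio scaling (0.0274) and without Ezh2cKO replicate 3 (0.0227).

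Cdkn2a (chromosome 4, 89274471 to 89294653), a locus that encodes a cell cycle inhibitor and the p53 activator ARF, was higher in Ezh2cKO cells of both cell types that listed it. In pro-B cells it rose from 0.311 ± 0.202 to 7.16 ± 3.59 CPM (log2 fold change 2.58, adjusted p = 0.000251). In DN3 cells no control library held a read and the Ezh2cKO libraries held 2.48 ± 0.672 CPM (n = 3, adjusted p = 4.11e-06). This was at least 36.7-fold higher than a floor of 3 reads over the control group, which covers counting error only. Cdkn2a lay below the minimum of the fit on RPKM in both cell types and was tested on CPM only.

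**Figure D1:**
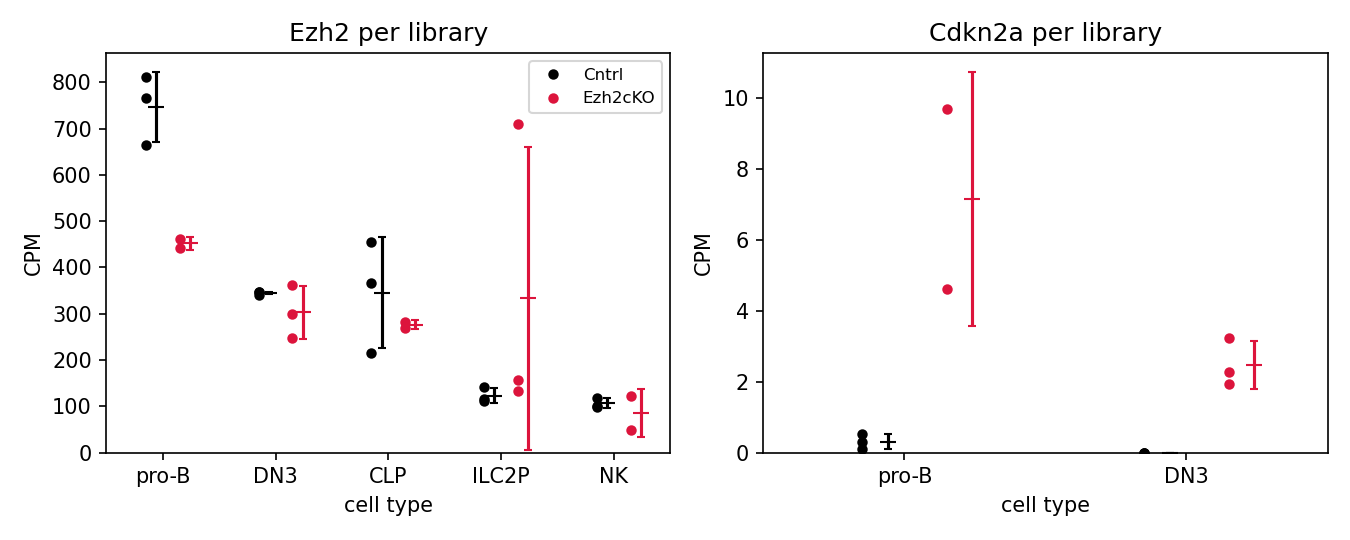
Ezh2 in the 5 cell types and Cdkn2a in pro-B and DN3 cells, in CPM per library (points; black for control, red for Ezh2cKO), with the mean and SD of each group beside them. Cdkn2a lies above every control in each Ezh2cKO library, and the library labelled ILC2P Ezh2cKO replicate 3 holds Ezh2 at 711 CPM.

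In pro-B cells, which rearrange the immunoglobulin heavy chain, many genes that were nearly silent in controls were transcribed in Ezh2cKO cells. The largest rises included the splicing factor Rbfox2 (chromosome 15, 77078990 to 77307053), from 0.0967 ± 0.0658 to 26.1 ± 6.02 CPM (log2 fold change 4.61, SE 0.25, adjusted p = 1.19e-05), and Zmat3 (chromosome 3, 32334796 to 32365678), a p53-induced RNA-binding protein, from 7.34 ± 1.43 to 154 ± 41.9 CPM (log2 fold change 4.20, adjusted p = 1.19e-05). Among the others were Tjp1, a scaffold of tight junctions (0.803 to 32.6 CPM), Tead1, a transcription factor of the Hippo pathway (2.41 to 50.6 CPM), the protease inhibitor Serpine2 (1.80 to 42.9 CPM), Peli2 (0.789 to 25 CPM) and Mpped2 (0.367 to 19.05 CPM). Kirrel, an adhesion protein, had 2 reads in the 3 controls and 532 in Ezh2cKO, a ratio of 430 with a 95% counting interval of 118 to 3560. The largest falls were in the calcium channel subunit Cacna2d1 (chromosome 5, 15934691 to 16374511), from 31.6 ± 6.5 to 2.16 ± 0.692 CPM (log2 fold change -3.37, adjusted p = 1.92e-05), and in Il2ra, which encodes CD25 (50.1 to 4.75 CPM). The Fc receptor-like genes Fcrl6 (23.3 to 1.72 CPM) and Fcrla (116 to 14.9 CPM), the IgM receptor gene Faim3 (25.7 to 4.23 CPM), the DNA polymerase Polm (26.96 to 2.90 CPM), the Ras activator Rasgrp1 (78.0 to 12.4 CPM) and Agbl1 (11.7 to 1.12 CPM) completed the 8. Without Ezh2cKO replicate 1 the calls of Faim3 and Agbl1 were lost (adjusted p = 0.0876 and 0.0545). Of these 16 genes, Zmat3, Il2ra, Fcrl6, Fcrla, Faim3, Polm and Rasgrp1 were past the minimum of the fit on RPKM, which also called them.

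Limma-trend on CPM called 1612 of 13453 genes in pro-B cells at an adjusted p below 0.05, 1267 higher and 345 lower in Ezh2cKO. Of these, 1057 and 241 differed by at least 2-fold, and in 39.8% of the higher genes the control mean lay below 1 CPM. All 1612 had no overlap between genotypes, which chance gives for 20% of genes and which 35.0% of the tested genes showed. The CPM scale departs from the fit fixed before the data were examined and was chosen after values had been seen, though before any fit. The fixed fit used the deposited RPKM, with a minimum of 1 RPKM in 2 libraries, and called 300 of 6971 genes, 122 higher and 178 lower; 280 of them were also called on CPM, none with the other sign. The direction of the split therefore turned with the filter: on CPM, the genes past the RPKM minimum gave 121 higher and 184 lower, and on RPKM without that minimum the split was 799 higher and 219 lower. Leaving out Ezh2cKO replicate 1 or 2 brought the CPM count to 942 or 963. In the authors' deposited table, 1354 genes were higher and 494 lower at an adjusted p below 0.05.

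**Figure D2:**
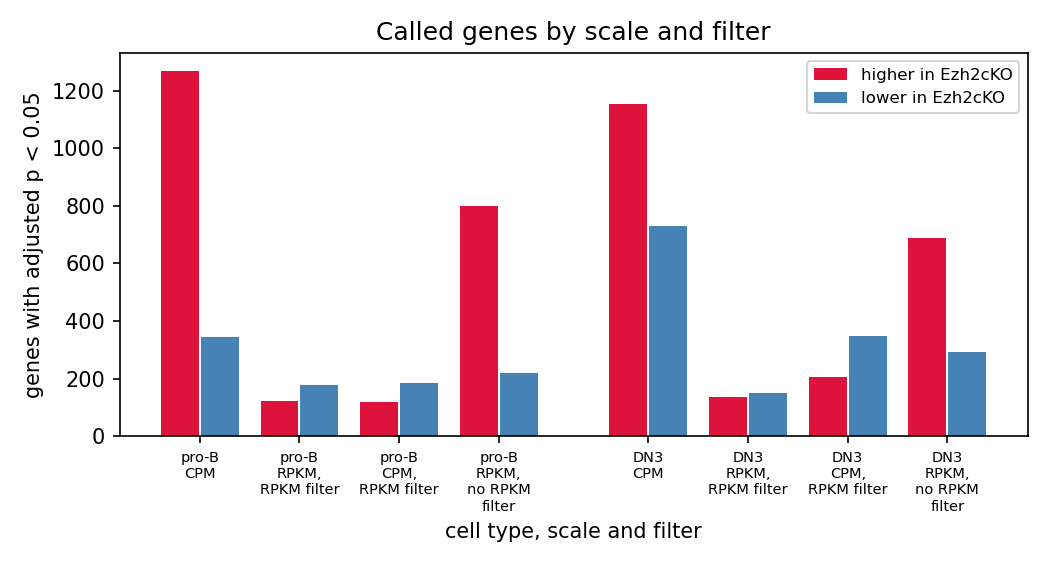
Genes with an adjusted p below 0.05 (vertical axis) in pro-B and DN3 cells, higher (red) and lower (blue) in Ezh2cKO, on CPM, on RPKM with the RPKM minimum, on CPM over the genes past that minimum, and on RPKM without it. In pro-B cells 1267 genes were higher and 345 lower on CPM, against 122 and 178 on RPKM with its minimum.

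Among the lists fixed before the data were examined, those of cell cycle inhibitors, p53 targets and developmental regulators had members that rose in pro-B cells. By fry, CDK inhibitors (adjusted p = 0.00172), p53 targets (0.0425), Hox genes (0.0352), other developmental factors (0.00172) and fetal genes (0.00323) were higher. Of 7 CDK inhibitors, 4 rose and none fell, also adjusted over the list alone: Cdkn1a went from 38.8 ± 11.3 to 136 ± 22.7 CPM, Cdkn2b from 0.618 to 5.85 CPM and Cdkn1c from 0.548 to 7.80 CPM, besides Cdkn2a (camera adjusted p = 0.0147; adjusted p = 0.377 with an estimated correlation). Of 22 p53 target genes 11 rose and 1 fell (14 and 1 adjusted over the list alone), among them Ccng1 (89.2 to 261 CPM) and the death receptor Fas (2.36 to 11.1 CPM; camera adjusted p = 1.95e-06; adjusted p = 0.377 with an estimated correlation). Of the 6 listed Hox genes 5 rose, and 6 adjusted over the list alone. Here Hoxa9 went from 0.781 to 6.68 CPM and Hoxa7 from 5.02 to 15.0 CPM (camera adjusted p = 1.12e-05; adjusted p = 0.377 with an estimated correlation). Only 3 Hox genes were called without Ezh2cKO replicate 1 and 2 without replicate 2, and Hoxa7 in neither. Of 10 other developmental transcription factors, 8 rose on both adjustments, such as the homeobox gene Lhx2 (0.835 to 10.5 CPM) and Satb2 (4.01 to 18.3 CPM; camera adjusted p = 2.56e-07; adjusted p = 0.142 with an estimated correlation). Leaving out control replicate 1, 1 of them was also called lower. Of 10 fetal haematopoietic and imprinted growth genes 8 rose (9 adjusted over the list alone), with the fetal RNA-binding proteins Lin28b (0.292 to 16.1 CPM) and Igf2bp3 (69.3 to 174 CPM; camera adjusted p = 4.91e-09; adjusted p = 0.142 with an estimated correlation).

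The B lineage list moved the other way in pro-B cells: 11 of 42 genes fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p = 5.22e-06; adjusted p = 0.377 with an estimated correlation). By fry the list did not pass (adjusted p = 0.0964). Members that fell were the surface receptor Cd72 (176 ± 16.8 to 44.2 ± 8.1 CPM), the kinase Blk (126 to 25.5 CPM), Irf4, a transcription factor of B cell maturation (505 to 200 CPM), and Il2ra. Of 19 mature B and plasma cell markers 5 fell (6 adjusted over the list alone), including Ms4a1, which encodes CD20 (43.4 to 19.5 CPM), and Cd22 (87.3 to 37.5 CPM; camera adjusted p = 0.0035; adjusted p = 0.464 with an estimated correlation). Without Ezh2cKO replicate 1, 7 B lineage genes and 2 mature B markers were called lower, and without either Ezh2cKO library no B lineage gene was called higher. Of 25 lymphoid progenitor genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone), with the stem cell factor receptor Kit at 24.4 CPM in controls and 103 CPM in Ezh2cKO and Hlf at 1.07 and 8.72 CPM, while Lmo4 fell from 84.1 to 19.8 CPM. This list did not pass as a set (camera adjusted p = 0.435), and without Ezh2cKO replicate 1 only 3 members were called higher. Cd19 and Il2ra products are part of the sorting gates or of stage definitions, so a level of such a gene also reflects the gate.

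Interferon-stimulated genes had 5 of 29 higher in pro-B cells, also adjusted over the list alone, led by Ly6a (8.81 ± 3.74 to 82.1 ± 53.7 CPM) and Iigp1 (3.15 to 32.7 CPM; camera adjusted p = 0.0167; adjusted p = 0.464 with an estimated correlation). The set did not pass without control replicate 3 (adjusted p = 0.0546) or Ezh2cKO replicate 2 (0.113), and 3 members were called without control replicate 1 or 3 or Ezh2cKO replicate 1. Both genes belong to families of similar copies between which reads can be split. T lineage genes had 1 of 35 higher and 4 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.00351; adjusted p = 0.655 with an estimated correlation; adjusted p = 0.116 without Ezh2cKO replicate 1). Tox fell from 29.1 to 8.52 CPM and Lck from 21.8 to 8.03 CPM. Without control replicate 1, 7 T lineage genes were lower, and without control replicate 1 or 3 or either Ezh2cKO library none was higher. None of 32 proliferation genes passed (camera adjusted p = 0.0805). Apoptosis regulators had 3 of 12 higher, 5 adjusted over the list alone, among them the p53 target Pmaip1 (2.47 to 19.4 CPM). Of these, 1 was called without Ezh2cKO replicate 2, and the set (camera adjusted p = 0.0659) passed without control replicate 2 (0.0275) or Ezh2cKO replicate 1 (0.0167). The counts higher and lower were 0 and 1 of 11 PRC2 subunits (Ezh2), 1 and 2 of 24 antigen receptor response genes, 3 and 1 of 22 ILC2 genes, 2 and 3 of 23 NK genes, 2 and 0 of 10 polarity regulators and 1 and 0 of 22 immediate early genes. Adjusted over the list alone they were 0 and 0, 3 and 3, 3 and 2, 3 and 3, 3 and 1, and 1 and 0. None of 11 mitochondrially encoded genes passed singly (camera adjusted p = 0.0179, lower; adjusted p = 0.464 with an estimated correlation). Each library left out changed at least 1 of these small counts. Without Ezh2cKO replicate 1, antigen receptor response genes had 1 and 1, NK genes 2 and 1 and polarity regulators 1 and 0, and without replicate 2 they had 0 and 2, 1 and 2, and 1 and 1. Without control replicate 1 they had 0 and 1, 1 and 4, and 1 and 0; without control replicate 2, NK genes had 1 and 3 and ILC2 genes 3 and 2; and without control replicate 3, antigen receptor response genes had 0 and 1 and polarity regulators 1 and 0. Markers of other cell types had 0 and 2 of 11 for myeloid cells (Cybb and Ms4a6c), 1 and 0 of 5 for erythroid cells (Car2), 0 and 2 of 9 for mature T cells (Ccr7 and Trac), 3 and 1 of 9 for dendritic cells, and none of 1 megakaryocyte, 3 basophil, 9 stromal and 6 sex-linked genes. Adjusted over the list alone these counts were the same. As sets, the PRC2 (adjusted p = 0.0316), myeloid (0.0134) and mature T (0.000769) lists were lower with the preset correlation, and with an estimated correlation their adjusted p were 0.377, 0.655 and 0.464. The PRC2 set did not pass without control replicate 1 or 2 or Ezh2cKO replicate 2, and the myeloid set did not pass without control replicate 3 or Ezh2cKO replicate 2. Without control replicate 1, 5 myeloid, 4 mature T and 2 basophil markers were called lower (camera adjusted p = 0.00189 for the last). Without any of the other libraries, Ezh2cKO replicate 1 (0) included, at most 1 mature T marker was called. Ms4a6c was not called without control replicate 3 or either Ezh2cKO library or by voom (adjusted p = 0.0529), Car2 not without control replicate 3 or Ezh2cKO replicate 1 or on RPKM (0.0866), and dendritic markers had 0 higher without Ezh2cKO replicate 1, 1 without replicate 2 and 2 without control replicate 1. Trac was not called without control replicate 2 or 3 or either Ezh2cKO library. An erythroid marker was lower without control replicate 1, and a mature B marker was higher without control replicate 2. The NK set passed without control replicate 1 (adjusted p = 0.0488). Immediate early genes passed without control replicate 2 (5 higher, adjusted p = 0.00118) or Ezh2cKO replicate 1 (0.00199), and had 0 higher and 1 lower without Ezh2cKO replicate 2. The polarity set passed without control replicate 2 (0.0471) or Ezh2cKO replicate 1 (0.00835).

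On deposited RPKM with its minimum, fewer members of most lists were tested in pro-B cells. Higher and lower counts were 3 and 0 of 6 CDK inhibitors (camera adjusted p = 0.00407), 6 and 1 of 14 p53 targets (2.47e-08), 1 and 0 of 7 apoptosis regulators (0.019), 1 and 0 of 12 interferon-stimulated genes (0.00388) and 1 and 0 of 17 immediate early genes (0.0319). They were 1 and 8 of 40 B lineage genes (0.00505), 0 and 4 of 13 mature B markers (0.0243), 0 and 1 of 3 mature T markers (0.019) and 0 and 1 of 5 ILC2 genes (0.0103, lower). Past the minimum were 1 Hox gene and 2 fetal genes, all called higher, and none of the other developmental transcription factors. The sets of PRC2 subunits (0 and 0 of 9, 0.453), T lineage genes (1 and 1 of 17, 0.621), lymphoid progenitor genes (3 and 1 of 17, 0.453), myeloid markers (0 and 0 of 4, 0.481) and mitochondrially encoded genes (0.109) did not pass. Antigen receptor response genes had 0 and 2 of 15, NK genes 1 and 0 of 7, dendritic cell markers 1 and 1 of 4, and polarity regulators and erythroid markers 0 of 1 and 0 of 2. With median-ratio scaling on CPM, 3 interferon-stimulated genes and 1 NK gene were higher, no antigen receptor response gene was, and 2 lymphoid progenitor and 2 ILC2 genes were lower, the latter also by voom.

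In DN3 thymocytes the largest rises were in genes with hardly any transcript in controls. Bmpr1a (chromosome 14, 34410734 to 34503341), a receptor for bone morphogenetic proteins, went from 0.495 ± 0.0515 to 40.4 ± 8.14 CPM (log2 fold change 4.78, SE 0.22, adjusted p = 1.52e-14), and the netrin receptor Neo1 (chromosome 9, 58874679 to 59036441) from 0.0927 ± 0.048 to 20.7 ± 4.46 CPM (log2 fold change 4.30, adjusted p = 2.25e-13). Bex1 (0.540 to 26.4 CPM), the metallothionein Mt1 (0.378 to 22.4 CPM), the phosphatase Ptpn13 (6.17 to 97.1 CPM) and Dmxl2 (0.324 to 16.3 CPM) followed. Cecr2 (1.52 to 53.2 ± 44.8 CPM) and Adam19 (0.439 to 22.0 ± 12.2 CPM) were also called, and pro-B controls held them at 881 and 47.0 CPM. The largest falls were in the lectin receptor Clec12a (20.8 ± 4.39 to 3.44 ± 0.798 CPM, log2 fold change -2.29, adjusted p = 7.45e-09), the neurexin gene Nrxn1 (17.1 to 3.57 CPM), the sodium-calcium exchanger Slc8a1 (18.5 to 3.75 CPM), Scin (41.8 to 14.5 CPM), Wwox (994 to 294 CPM), Gpr174 (20.7 to 6.38 CPM), Slc9a9 (864 to 293 CPM) and Cd163l1 (23.2 to 7.68 CPM). Of these 16 genes, Bex1, Mt1, Wwox, Slc9a9 and Cd163l1 were past the minimum of the fit on RPKM, which also called them.

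On CPM, 1885 of 13537 genes were called in DN3 cells, 1155 higher and 730 lower in Ezh2cKO, 714 and 98 of them by at least 2-fold. No overlap between genotypes held for 1790 of the calls and for 27.2% of the tested genes, against 10% by chance. The fit on deposited RPKM with its minimum called 289 of 7317 genes, 138 higher and 151 lower, of which 266 were called on CPM, none with the other sign. On CPM the genes past that minimum gave 205 higher and 349 lower, and on RPKM without it 690 were higher and 294 lower, so the direction of the split turned with the filter here too. It turned as well without Ezh2cKO replicate 3, which left 1002 higher and 1331 lower. Same-numbered DN3 libraries deviated together, and with the replicate number as a block 2864 genes were called, 1470 higher and 1394 lower. In the authors' deposited table, 1464 genes were higher and 990 lower at an adjusted p below 0.05.

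Interferon-stimulated genes were the group with the most called members in DN3 cells: 22 of 29 rose and none fell (26 adjusted over the list alone). Iigp1 went from 8.12 ± 3.03 to 29.2 ± 9.7 CPM, Oas1a from 4.81 to 18.0 CPM, Ly6a from 14.6 to 37.7 CPM and Ifi44 from 9.36 to 31.3 CPM (camera adjusted p = 2.04e-14; adjusted p = 0.867 with an estimated correlation, as these genes vary together between libraries). Without Ezh2cKO replicate 3, 14 were called. By fry the interferon set did not pass (adjusted p = 0.239), while CDK inhibitors (0.00515), p53 targets (0.00181) and fetal genes (0.0158) were higher. Of 7 CDK inhibitors 4 rose (5 adjusted over the list alone), with Cdkn2c going from 14.3 ± 2.01 to 30.6 ± 7.08 CPM, Cdkn2b from 0.120 to 2.04 CPM and Cdkn1c from 0.262 to 1.74 CPM (camera adjusted p = 0.000615; adjusted p = 0.151 with an estimated correlation). Of 23 p53 target genes 10 rose and none fell (13 and 1 adjusted over the list alone), among them Zmat3 (17.2 to 116 CPM), the apoptosis inducer Pmaip1 (2.37 to 14.3 CPM) and Fas (3.68 to 9.10 CPM; camera adjusted p = 0.000122; adjusted p = 0.151 with an estimated correlation). Without control replicate 2 or Ezh2cKO replicate 3, 1 p53 target was called lower, and with the block 13 were higher and 1 lower. Of 11 fetal and imprinted growth genes 7 rose (8 adjusted over the list alone), with H19 at 95.7 and 230 CPM and Plagl1 at 0.295 and 4.46 CPM (camera adjusted p = 1.71e-05; adjusted p = 0.151 with an estimated correlation). Proliferation genes had 3 of 32 higher, Rrm2 (140 to 201 CPM), Birc5 (43.7 to 62.1 CPM) and Cdk1 (52.6 to 74.8 CPM), and 13 adjusted over the list alone (camera adjusted p = 1.71e-05; adjusted p = 0.982 with an estimated correlation). That count was 18 with the block and 19 with median-ratio scaling, 7 without Ezh2cKO replicate 2, 1 without control replicate 3 or Ezh2cKO replicate 1, and 0 without control replicate 2 or Ezh2cKO replicate 3. On RPKM all 3 calls were lost (adjusted p = 0.196 for Rrm2, 0.138 for Birc5 and 0.167 for Cdk1), and by voom that of Cdk1 was (0.0516).

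In the comparison of DN3 cells, 15 of 39 B lineage genes were called higher in Ezh2cKO and none lower (16 and 2 adjusted over the list alone; camera adjusted p = 0.00297; adjusted p = 0.982 with an estimated correlation), and the rise lay mainly in replicate 3 and to a lesser extent in replicate 1. Over 26 genes with more than 100 CPM in pro-B controls and under 2 CPM in DN3 controls, the median share of the pro-B control level was 10.9% in Ezh2cKO replicate 3, 1.23% in replicate 1 and 0.230% in replicate 2, against 0.0550% to 0.122% in the controls. Ebf1, a transcription factor of B cell commitment, stood at 213 CPM in replicate 3, 21.4 CPM in replicate 1 and 1.07 CPM in replicate 2. Without replicate 3, 7 B lineage genes were called higher and 9 lower (camera adjusted p = 0.566), and with median-ratio scaling 4 were called higher and the set did not pass (camera adjusted p = 0.116). By voom 6 were called higher, and on RPKM 1 of the 18 past its minimum (camera adjusted p = 0.135). Without control replicate 1, 15 were higher and 4 lower, and with the block 15 and 3. The named member Cd2 lay at 11.3, 7.93 and 11.6 CPM in the 3 Ezh2cKO libraries and at 1.36 to 1.78 CPM in controls. Mature B and plasma cell markers had 9 of 14 higher and 1 lower (10 and 1 adjusted over the list alone; 5 and 1 without replicate 3, 3 and 1 with median-ratio scaling, 4 and 1 by voom, 1 and 0 of 5 on RPKM, and none lower without control replicate 3 or Ezh2cKO replicate 1 or 2), with H2-Ab1 going from 5.72 to 20.6 CPM (camera adjusted p = 0.000122; adjusted p = 0.982 with an estimated correlation). Leaving out the 360 genes high in pro-B controls, 147 of them called higher and 7 lower, 1075 genes were higher and 837 lower.

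**Figure D3:**
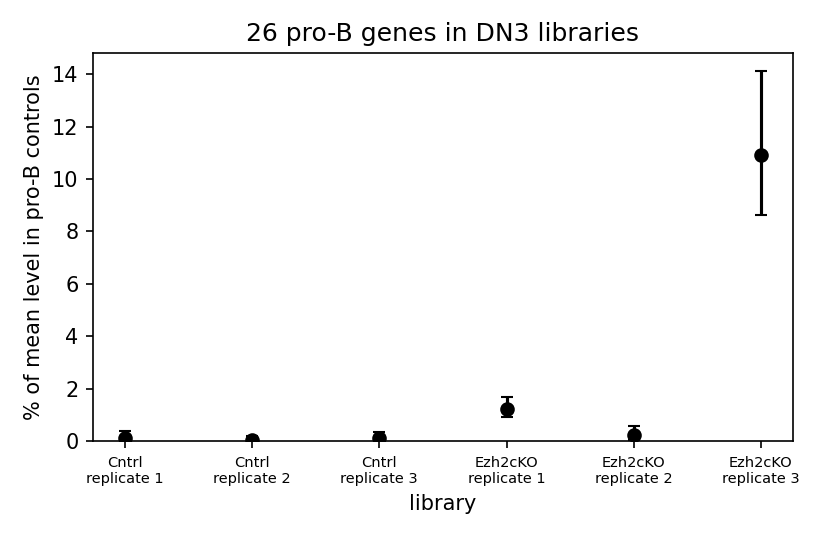
Level of 26 genes of pro-B cells in each DN3 library, as a percent of their mean in pro-B controls (point, median over the genes; bars, quartiles). Ezh2cKO replicate 3 lies at 10.9%, and the other 5 libraries lie between 0.0550% and 1.23%.

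T lineage genes had 2 of 42 higher and 5 lower in DN3 cells, also adjusted over the list alone. Themis, a signalling protein of thymocyte selection, fell from 809 ± 63.5 to 435 ± 31.9 CPM, the kinase Itk from 153 to 86.4 CPM and Tox from 417 to 246 CPM, and Dtx1, a Notch target, rose from 45.0 to 97.8 CPM. The list did not pass as a set (camera adjusted p = 0.175), and with the block 4 members were higher and 11 lower. Without Ezh2cKO replicate 3, 1 was higher and 8 lower. Lymphoid progenitor genes had 4 of 24 higher and 2 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.778), with Meis1 at 0.565 and 5.55 CPM and Ccr9 at 170 and 75.4 CPM, and without Ezh2cKO replicate 3 they had 2 higher and 10 lower. The block gave them 4 higher and 9 lower, and without control replicate 1 they had 3 higher and 6 lower. Without control replicate 2 or Ezh2cKO replicate 1, 1 was lower. Among apoptosis regulators, 3 of 12 were higher and 1 lower (4 and 1 adjusted over the list alone), and the survival factor Bcl2 fell from 448 ± 83.1 to 241 ± 57.1 CPM. Higher and lower counts were 6 and 1 of 25 ILC2 genes, 3 and 1 of 22 NK genes, 3 and 1 of 26 antigen receptor response genes, 1 and 1 of 13 polarity regulators, 1 and 0 of 11 PRC2 subunits (Phf19), 0 of 3 Hox genes and 1 of 1 developmental transcription factor (Satb2). Adjusted over the list alone, ILC2 genes had 7 and 1, antigen receptor response genes 3 and 2 and PRC2 subunits 0 and 0, and the other 4 lists kept those counts. The antigen receptor and ILC2 sets passed without control replicate 2 (camera adjusted p = 0.0158 and 0.0452) or Ezh2cKO replicate 1 (0.0358 for both), with 7 and 6 antigen receptor response genes higher and none lower. Without control replicate 1 that list had 3 lower and without control replicate 3 none. NK genes had 2 and 4 without control replicate 1, 1 and 1 without control replicate 3, 2 and 0 without Ezh2cKO replicate 2 and 2 and 5 without replicate 3, where ILC2 genes had 6 and 2. The lower polarity regulator was not called without control replicate 1 or 3 or Ezh2cKO replicate 2. Phf19 was not called without any library other than Ezh2cKO replicate 2, or on RPKM (log2 fold change 0.27, adjusted p = 0.126). The block gave antigen receptor response genes 7 and 2, ILC2 genes 9 and 3, NK genes 4 and 4, mature T cell markers 3 and 2, stromal markers 1 and 2 and PRC2 subunits 1 and 1. Markers of other cells had 0 and 1 of 6 for myeloid cells (Ms4a6c), 1 and 0 of 4 for erythroid cells (Epor), 2 and 0 of 16 for mature T cells (Icos and Ccr7), 0 and 2 of 8 for dendritic cells (Ccr9 and Tcf4), 1 and 1 of 4 for stroma (Pdgfrb and Pecam1) and none of 2 megakaryocyte, 2 basophil and 6 sex-linked genes. Adjusted over the list alone, erythroid markers had 2 and 1 and stromal markers 1 and 2. Ms4a6c was not called without control replicate 3 or Ezh2cKO replicate 1 or 2, Icos not without control replicate 1 or 2 or Ezh2cKO replicate 1 or 2, Ccr7 not without control replicate 2 or Ezh2cKO replicate 2 or 3 or with median-ratio scaling (adjusted p = 0.0665), Tcf4 not without any library other than Ezh2cKO replicate 3, and Pdgfrb and Pecam1 not without Ezh2cKO replicate 2 (adjusted p = 0.0518 and 0.0536) or on RPKM (0.0717 and 0.111). By voom Ms4a6c (0.0586), Ccr7 (0.0505) and Tcf4 (0.0603) were not called, and Tcf4 was not with a pseudocount of 0.1 (0.0524). Sex-linked genes had 2 higher and 4 lower without control replicate 1 and 4 higher and 2 lower without Ezh2cKO replicate 1, where the basophil marker Cpa3 was also higher. Without Ezh2cKO replicate 3, 1 mature T and 2 stromal markers were lower. None of 23 immediate early and 12 mitochondrially encoded genes passed singly, and neither set passed (camera adjusted p = 0.175 for both). Immediate early genes passed with the block (7 higher, 0.0118), without control replicate 2 (10 higher, 3.47e-10) and without Ezh2cKO replicate 1 (8 higher, 6.09e-07). Mitochondrially encoded genes passed with the block (1 higher, 0.0333) and without Ezh2cKO replicate 3 (1 higher, 0.00173).

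On RPKM the DN3 lists kept fewer calls. Higher and lower counts were 12 and 0 of 22 interferon-stimulated genes (camera adjusted p = 1.2e-18), 1 and 0 of 4 CDK inhibitors (0.044), 2 and 0 of 11 p53 targets (0.000119), 0 of 32 proliferation genes (1.64e-10, higher) and 1 and 0 of 5 mature B markers (0.021). Immediate early (0.021) and mitochondrially encoded genes (0.00811) passed as sets without a called member. Of the fetal genes 1 was past the minimum and called higher, and Satb2 was not past it. T lineage genes had 1 and 4 of 33, lymphoid progenitor genes 0 and 1 of 12, apoptosis regulators 1 and 1 of 8, antigen receptor response genes 2 and 0 of 15, ILC2 genes 0 and 1 of 11, dendritic cell markers 0 and 1 of 4 and stromal markers 0 and 0 of 3. None of 8 NK genes, 4 polarity regulators, 11 PRC2 subunits, 8 mature T, 2 myeloid and 1 erythroid markers was called. With median-ratio scaling on CPM, T lineage genes had 2 and 8, lymphoid progenitor genes 3 and 4, ILC2 genes 7 and 2, NK genes 2 and 2, antigen receptor response genes 4 and 0 (3 and 0 by voom), stromal markers 1 and 2 and PRC2 subunits 1 and 1, and 1 p53 target was lower and 1 Hox gene higher.

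In CLP, the earliest population, limma-trend called none of 13127 genes, and neither did voom or the fit on RPKM; 465 genes had an unadjusted p below 0.05, against 656 expected by chance. In the authors' deposited table, 5 genes were higher and 1 lower at an adjusted p below 0.05. Zmat3, the gene with the smallest p in pro-B cells, stood at 19.8 ± 12.5 CPM in control and 10.03 ± 2.77 CPM in Ezh2cKO CLP, and Bmpr1a at 0.717 and 1.67 CPM, neither past the test. No member of the 27 lists passed, adjusted over all genes or over the list alone. As sets, mitochondrially encoded genes (median log2 fold change 0.33, camera adjusted p = 0.000235), interferon-stimulated genes (0.30, 0.015), myeloid markers (0.62, 0.0402) and proliferation genes (0.12, 0.0476) were higher and lymphoid progenitor genes lower (-0.27, 0.0476). With an estimated correlation their adjusted p were 0.774, 0.774, 0.774, 0.859 and 0.774, and with median-ratio scaling the myeloid (0.0983) and lymphoid progenitor sets (0.125) did not pass. On RPKM the lymphoid progenitor set did not pass (0.177), immediate early genes did (higher, 0.03), and the other 4 sets passed. On CPM the mitochondrial set passed whichever of the 5 libraries was left out. The interferon set did not pass without control replicate 3 or Ezh2cKO replicate 2, the myeloid set without control replicate 1 or 3 or Ezh2cKO replicate 2, the proliferation set without control replicate 2 or 3 or Ezh2cKO replicate 1, and the lymphoid set without control replicate 1 or 3 or Ezh2cKO replicate 1. The median was -0.37 for myeloid markers without Ezh2cKO replicate 2 and -0.04 for proliferation genes without replicate 1. B lineage genes passed as lower without control replicate 2 (-0.41, 0.0463) or Ezh2cKO replicate 1 (-0.50, 0.000397) and as higher without Ezh2cKO replicate 2 (0.17, 0.0288). Immediate early genes passed without control replicate 1 (0.000442) or Ezh2cKO replicate 2 (0.000636), and ILC2 genes without Ezh2cKO replicate 1 (0.044). In simulated CLP data with these libraries' mean levels and the same dispersion for every gene, 47 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were recovered. The simulated spread was likely too small, so these figures do not show that 4-fold changes in CLP would nearly all be called.

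In ILC2P the only call among 13164 genes was the immunoglobulin heavy chain gene Igha, which lay at 209, 1160 and 1170 CPM in controls and at 0, 0 and 1.41 CPM in Ezh2cKO (log2 fold change -8.94, adjusted p = 0.00512). It was not called by voom, with a pseudocount of 0.1, or without control replicate 2 or 3, and 621 genes had an unadjusted p below 0.05 against 658 expected. The fit on RPKM called 2 genes, both lower, and the authors' deposited table held 22 higher and 11 lower at an adjusted p below 0.05. The library labelled Ezh2cKO replicate 3 stood apart. It held Gata3, the defining transcription factor of ILC2, at 4 CPM against 535 to 1120 CPM in the other 5 libraries, and Flt3, a cytokine receptor of early progenitors, at 1210 CPM against 2.32 to 45.0 CPM. Across 11021 genes, which are not independent replicates, its correlation with the control mean was 0.699 for ILC2P and 0.862 for CLP. The CLP libraries themselves correlated with the CLP control mean at 0.917 to 0.95.

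The ILC2P lists moved with that library. ILC2 genes were lower (median log2 fold change -1.41, camera adjusted p = 4.3e-06) and proliferation genes (1.47, 3.24e-10), B lineage genes (1.04, 0.00102) and lymphoid progenitor genes (1.19, 0.00519) higher, and mature T cell markers were lower (-1.67, 0.00519); the adjusted p of each was 0.56 with an estimated correlation. On RPKM the lymphoid progenitor set did not pass (0.202) and the other 4 did. Without Ezh2cKO replicate 3 the median of the ILC2 genes was 0.01 (camera adjusted p = 0.732) and that of the lymphoid progenitor genes 0.06 (0.856), while proliferation genes (0.39, 0.00577), B lineage genes (0.30, 0.0436) and mature T cell markers (-0.89, 0.00868) still passed, and interferon-stimulated genes passed as well (0.39, 0.00577). Without that library 6 genes were called, 1 higher and 5 lower, and 3 mature B and plasma cell markers were lower. Interferon-stimulated genes also passed without control replicate 2 (0.0447) or Ezh2cKO replicate 1 (0.0411), polarity regulators without Ezh2cKO replicate 1 (0.0317) or 2 (0.0443), and mature B markers without control replicate 1 (0.0119, with 2 lower) or Ezh2cKO replicate 1 (0.0317). T lineage (0.00958) and immediate early genes (0.0132) passed without Ezh2cKO replicate 1. Besides Igha, no member of a list passed over all genes. Adjusted over the list alone, the mature B and plasma cell markers Igha, Igkc and Igj and the lymphoid progenitor gene Lmo4 were lower and the B lineage gene Igll1 was higher. In simulated ILC2P data 5 of 100 genes changed 2-fold and 72 of 100 changed 4-fold were recovered, so changes of 2-fold were mostly not detectable at the simulated spread. That spread took in the library labelled Ezh2cKO replicate 3, so recovery among the other ILC2P libraries was not tested.

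In splenic NK cells no gene of 12692 was called by limma-trend, by voom or on RPKM; 480 had an unadjusted p below 0.05 against 635 expected, and the authors' deposited table held 3 higher and 5 lower at an adjusted p below 0.05. Of 50 NK maturation and effector genes none passed, and their median log2 fold change was 0.08 (camera adjusted p = 0.334). Control replicate 3 differed from the other NK libraries: it held the T cell receptor component Cd3e at 309.8 CPM against at most 7.29 CPM in the other 4, and Cd3d at 85.3 CPM against at most 2.06 CPM. As sets, interferon-stimulated genes were higher (median 0.48, camera adjusted p = 0.0148), and mature T cell markers (-0.75, 0.0148), mitochondrially encoded genes (-0.23, 0.0148), proliferation genes (-0.43, 0.0198), B lineage genes (-0.38, 0.023), lymphoid progenitor genes (-0.37, 0.0283) and T lineage genes (-0.04, 0.0399) lower. Their adjusted p were between 0.762 and 0.83 with an estimated correlation. On RPKM the proliferation, mitochondrial and mature T sets passed (0.0482 for each), and the interferon (0.137), B lineage, T lineage and lymphoid progenitor sets (0.271 for each) did not. None of the 7 passed without control replicate 3, and 1 and 4 sets passed without Ezh2cKO replicates 1 and 2. Without control replicate 2 the proliferation (0.0559) and lymphoid progenitor sets (0.0779) did not pass, and without control replicate 1 the NK list passed (median 0.24, 0.0136). Adjusted over the list alone, 1 fetal gene was higher and 2 mature T cell, 1 T lineage, 1 B lineage and 1 mitochondrial gene were lower. Simulated NK data gave 13 of 100 genes changed 2-fold and 89 of 100 changed 4-fold, at a spread that was likely too small here too.

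Pro-B and DN3 cells shared a large part of the genes that rose. Of 12571 genes listed for both, 1022 rose in pro-B and 966 in DN3 cells, and 524 rose in both, against 78.5 for independent lists (odds ratio 26.4); leaving out any library of either cell type left between 379 and 513 shared. The RPKM fits had 6209 genes in common, of which 80 rose in each cell type and 24 in both, against 1.03 for independent lists. The genes with the smallest largest adjusted p over both cell types were Zmat3, Rbfox2, Kirrel, Mpped2, Serpine2, Cdc42bpa, Atp11a, Chn1, Fzd3 and Bmpr1a. Fzd3, a Wnt receptor, went from 0.232 ± 0.15 to 13.5 ± 1.51 CPM in pro-B and from 0.752 ± 0.279 to 17.4 ± 3.82 CPM in DN3 cells, and Cdc42bpa, a kinase of the actin cytoskeleton, from 22.1 to 147 and from 19.7 to 91.9 CPM. Only 20 genes fell in both, against 11.9 for independent lists (Fisher's exact test, unadjusted p = 0.0156, adjusted p = 0.156 over 20 overlaps of 10 pairs of cell types). The other cell types gave lists of at most 1 gene, so their overlaps tested nothing and only added to the adjustment. The 2 comparisons share no library, but same-numbered libraries of both cell types had the same pattern of Xist and Y-linked transcripts. The labels do not say whether they came from the same animals, so the 2 comparisons are not known to be independent, as the expected overlaps and the test of differences below take them to be.

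**Figure D4:**
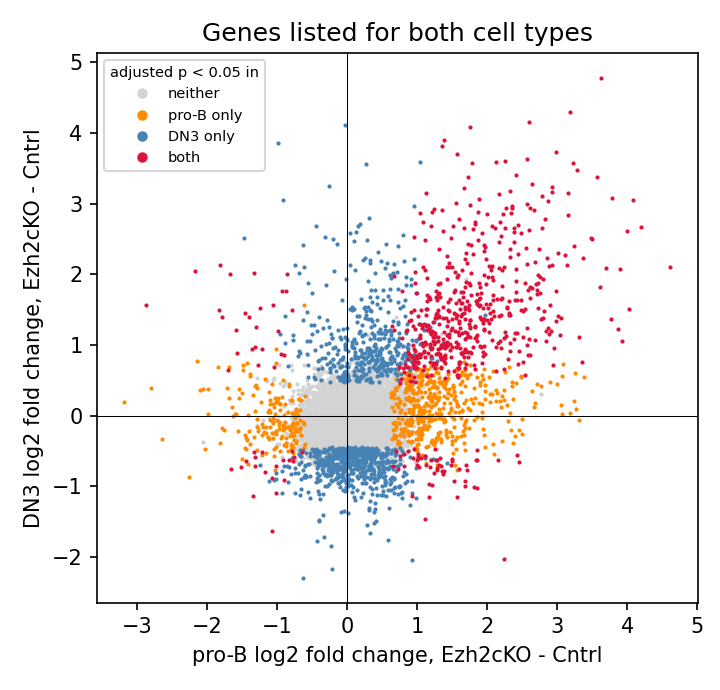
Log2 fold changes (Ezh2cKO minus control, log2(CPM + 1) scale) in pro-B (horizontal axis) and DN3 cells (vertical axis) of the 12571 genes listed for both, each point a gene, coloured by where its adjusted p lay below 0.05. Among genes called in both cell types 544 lie in the quadrants of equal sign, 524 of them higher in both, and 84 in those of opposite sign.

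The genotype effect itself differed between pro-B and DN3 cells for 881 of the 12571 genes, 615 with a larger and 266 with a smaller value in pro-B cells (difference of the log2 fold changes over their combined standard error, adjusted p below 0.05). This test and the overlap above used the DN3 fit without the replicate block, and neither was run with it. Slc8a1 rose in pro-B (3.98 to 22.1 CPM) and fell in DN3 cells (18.5 to 3.75 CPM), a difference of 4.26 (SE 0.33). Heyl, a Notch target, fell in pro-B (34.5 to 7.11 CPM) and rose in DN3 cells (2.92 to 15.5 CPM), a difference of -4.21 (SE 0.38), and Myl4 did likewise (99.8 to 32.4 and 2.85 to 8.54 CPM, difference -2.79). Spats2 rose in pro-B cells (0.118 to 10.1 CPM) and stood at 89.0 and 85.3 CPM in DN3 cells, a difference of 3.37. Dennd5b (difference -3.12), Cecr2 (-4.14) and Adam19 (-4.85) rose in DN3 cells and were not called in pro-B cells (Adam19 was without control replicate 2, adjusted p = 0.0368), whose controls held 113, 881 and 47.0 CPM of them. Zfhx3 rose in pro-B cells (9.42 to 101 CPM) and stood at 150 and 80.4 CPM in CLP, a difference of 4.25 (SE 0.40). Without Ezh2cKO pro-B replicate 1 or 2, the count of genes that differed between pro-B and DN3 cells was 436 or 461, and on RPKM 85 genes differed.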

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

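The tests of depth and of B lineage and B cell RNA, in ILC2P and in DN3 cells, the scaling with the replicate block, the DN3 fit without genes high in pro-B controls and the tests of differences between cell types were chosen after the results were seen. The genotype effect differed between cell types for 881 genes between pro-B and DN3 cells, 158 between pro-B cells and CLP, 42 between pro-B and NK cells, 26 between pro-B cells and ILC2P, 40 between DN3 cells and CLP, 10 between DN3 and NK cells, 7 between DN3 cells and ILC2P and 1 between ILC2P and NK cells. No gene differed between CLP and ILC2P or between CLP and NK cells by the same limma-based test, where 562 and 422 genes had an unadjusted p below 0.05. The genes with the smallest p were Slc8a1 (difference of log2 fold changes, pro-B minus DN3, 4.26), Dennd5b (-3.12), Cecr2 (-4.14), Heyl (-4.21), Spats2 (3.37), Adam19 (-4.85) and Myl4 (-2.79), and Zfhx3 (pro-B minus CLP, 4.25).

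The library labelled ILC2P Ezh2cKO replicate 3 held Gata3 at 4 CPM, Il1rl1 at 2.37 CPM and Rora at 1.41 CPM, within the range of CLP controls for each, against at least 535, 990 and 754 CPM in the other ILC2P libraries, and Flt3 at 1210 CPM and Dntt at 1930 CPM, against at most 45.0 and 158 CPM. CLP controls held 804 to 992 CPM of Flt3 and 2130 to 2570 CPM of Dntt, so neither value lay within their range. Depth is argued against, as the library's total was 1.01 times the highest of the others; thinning it to their lowest total left the correlation with the ILC2P control mean at 0.699, as before, and so tested nothing. CD19-positive B lineage cells are argued against as well: Ebf1 stood at 74.8% of its pro-B control level, but those of Cd19 and Cd79a were at most 3.84% of that share. RNA of another sorted population may account for the pattern, since the library's best match was CLP (correlation across genes 0.862, the only library of 27 not closest to its own type). The match was weaker than that of any CLP library (0.917 to 0.95), and pro-B controls also reached 0.862 to 0.887 with CLP. No CLP library was out of place, so an exchange with a CLP library of the series was not seen. A single library labelled or sorted wrongly would leave no such trace and stays open, as the series holds no CLP Ezh2cKO replicate 3. The library held both Xist (911 CPM) and Y-linked transcripts (147 CPM). So did control replicate 3 of ILC2P (833 and 141 CPM) and of CLP (1450 and 159 CPM), so these transcripts do not settle its origin. No biological explanation was tested, and a block of differentiation in this library stays open.

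The DN3 Ezh2cKO replicate 3, and to a lesser extent replicate 1, held B lineage transcripts, while in replicate 2 Ebf1 stood at 1.07 CPM. RNA of B lineage cells may account for replicate 3, where the median share of the pro-B control level was 10.9% and 100% of the 26 genes lay no more than 3-fold below it. There Ebf1 stood at 213 CPM, Cd79a at 68.0 CPM, Pax5 at 64.3 CPM and Cd19 at 60.6 CPM. An even rise with the genotype is argued against, as the median share in replicate 2 was 2.11% of that in replicate 3. The lineage-negative gate of the DN3 sort would remove such cells. Whether some Ezh2cKO thymocytes transcribed B lineage genes was not tested and stays open.

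More genes were higher than lower on CPM in Ezh2cKO pro-B and DN3 cells, but in DN3 cells, where same-numbered libraries deviated together, the replicate block left 1470 higher and 1394 lower. Without the block, library scaling is argued against (the lower of the 2 ratios of higher to lower calls was 1.34 after median-ratio scaling), while with it the scaling widened the DN3 split, to 1877 higher and 1518 lower (ratio 1.24), from one too even to test. RNA of myeloid, erythroid, megakaryocyte, basophil, dendritic or stromal cells is argued against only as a rise of most of such a list. At most 33.3% of a list was higher (3 of 9 dendritic cell markers in pro-B cells, where 1267 of all 13453 genes were). The lists held 1 to 11 listed genes, so a smaller admixture stays open. Reads spread evenly over gene spans stay open too: genes not called rose by at most 3.54% of the median rise of genes called higher, but picking genes by their calls fixes much of that. RNA of B cells may account for part of the DN3 excess, as 64.3% of the mature B and plasma cell markers were higher there. Without genes high in pro-B controls, 1075 genes were higher and 837 lower, against 1155 and 730 with them. Without Ezh2cKO replicate 3 the split turned, but mostly by added lower calls. Higher calls went from 1155 to 1002 and lower calls from 730 to 1331. The median log2 fold change of all genes also moved, from -0.04 to -0.11, so the turn is weak evidence for added B cell RNA. The low-level filter, under which the split turned as well (122 higher and 178 lower in pro-B and 138 and 151 in DN3 cells), and a loss of EZH2 repression stay open and are not separated from these.

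For the counts of called genes, 3 against 3 libraries give 10 splits, too few for a share under 0.05: the real split gave 1885 genes in DN3 cells and the highest of the others 0, and in ILC2P the real split gave 1 and the highest of the others 0.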

How the results depend on the processing

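Median-ratio scaling for the calls and differences of genes (with limma, in DN3 cells also with the block), the DN3 fit without genes high in pro-B controls, the test of differences between cell types, and RPKM for lists, overlap and differences were added after the data were seen. For the set tests, median-ratio scaling was planned. The counts of called genes changed as follows. Log2 of RPKM with its minimum gave 300 in pro-B and 289 in DN3 cells and 2 in ILC2P; on CPM the genes past that minimum gave 305 and 554, so the genes tested account for part of the drop. A 2-fold minimum gave 812 in DN3 cells, which follows from its construction. In ILC2P voom gave 0 and the pseudocount of 0.1 gave 0. All 27 samples in one fit gave 31 in pro-B cells, 27 in DN3 cells, 99 in ILC2P and 42 in NK cells, with a spread shared over all cell types and 11021 genes. The replicate block gave 2864 in DN3 cells (3395 with median-ratio scaling as well, 1877 higher and 1518 lower), 1872 in pro-B cells, 1 in CLP and, by library code, 5 in NK cells. Outside DN3 cells the numbers were not taken to pair the libraries, as not every correlation was over 0.1 (0.30 and -0.01 in pro-B cells, 0.13 and 0.10 in CLP, 0.09, 0.02 and 0.09 in ILC2P, and -0.01 and 0.00 in NK cells). Same-numbered libraries (in NK cells by code) did share their pattern of Xist and Y-linked transcripts. In cell types with 2 Ezh2cKO libraries the deviations of these mirror each other, so the correlations cannot settle pairing there. Leaving out each library gave 942 to 1448 in pro-B cells, 1490 to 2333 in DN3 cells, 0 in CLP and NK cells and 0 to 6 in ILC2P, 436 to 970 for the genes that differ between pro-B and DN3 cells, and 379 to 513 shared higher genes. On RPKM 24 higher genes were shared and 85 differed.

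Of the camera set tests, 13, 7, 5, 5 and 7 passed in pro-B cells, DN3 cells, CLP, ILC2P and NK cells, and with an estimated correlation 0 passed in each. Leaving out each library gave 10 to 15 in pro-B cells, 7 to 11 in DN3 cells, 1 to 5 in CLP, 4 to 10 in ILC2P and 0 to 8 in NK cells. In CLP median-ratio scaling gave 3 (without myeloid and lymphoid progenitor genes) and the replicate block 2, without interferon-stimulated (adjusted p = 0.139), myeloid (0.0632) and proliferation genes (0.167). In NK cells RPKM gave 3 and the block by title number 0, while the block by library code was not run for sets. In pro-B cells proliferation (lower, camera adjusted p = 0.0062) and apoptosis genes (0.0314) passed with the replicate block and myeloid markers (0.0562) did not. Among 5580 values of 392 named genes by cell type, 5306 stayed on their side of the threshold, 256 lost the call, 16 gained it and 2 reversed. A reversal was counted only where the gene was called in the main or the alternative fit. A change of sign of an uncalled gene therefore stands among the 5306. The 2 reversals were Xist in DN3 cells (3.58 without control replicate 1, against -3.27 without Ezh2cKO replicate 1) and Uty in DN3 cells (1.27 without Ezh2cKO replicate 1, against -2.16 without control replicate 1). Without rescaling, among the named DN3 genes the replicate block changed the call of Ezh1 alone, and among the DN3 set tests those of immediate early and mitochondrially encoded genes. Except where stated, the cause was not tested. The comparison with no filter was void, as the minimum removed no gene. The alternatives on count models were not run, as the design named them for counts as deposited and the deposited values are RPKM, though voom was run on the recovered reads. Where a library left out leaves 1 in a group, it is assumed to vary like the other group. At the simulated spread 2-fold changes were mostly not detectable in ILC2P and NK cells.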

Other observations

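The tests of the set of 524 genes in this part were chosen after the results were seen, while the limma values of single genes come from the fits described above. The 524 genes higher in both pro-B and DN3 Ezh2cKO cells were followed in the other cell types, where no gene of the set was called in the fits per cell type. In CLP 384 of them were listed and 63.8% had a log2 fold change above 0, against 42.4% of all genes, with a median of 0.22 (camera adjusted p = 2.22e-06; adjusted p = 0.0527 with an estimated correlation). In NK cells 297 were listed and 70.7% lay above 0, against 53.1% of all genes, with a median of 0.46 (camera adjusted p = 2.22e-06; adjusted p = 0.286 with an estimated correlation). Without control replicate 3 the median was 0.24, with 62.6% above 0 against 47.9%. In ILC2P 375 were listed and 50.7% lay above 0, against 47.1% (camera adjusted p = 0.376), and without Ezh2cKO replicate 3 it was 57.1%, against 44.3%, with a median of 0.15 against -0.09 for all genes (camera unadjusted p = 0.00434; 0.0382 with an estimated correlation). Cdc42bpa, a member of the set, stood at 7.91 CPM in control and 71.2 CPM in Ezh2cKO NK cells (limma adjusted p = 0.998, and 0.00406 in the fit of all 27 libraries, with a log2 fold change of 3.33). That fit shares the spread of a gene over all cell types. The median residual SD was 0.865 in NK cells, against 0.256 in pro-B and 0.23 in DN3 cells, so the smaller p does not rest on the spread of NK libraries.

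Transcripts of the mature B and plasma cell markers Igha, Igkc and Igj were found in control ILC2P libraries. These 3 were picked after their values were seen, and the median log2 fold change of the 15 listed markers was -0.05. Igha had means of 846 ± 551 CPM in controls and 0.469 ± 0.813 CPM in Ezh2cKO, Igkc means of 1215 and 0.198 CPM (limma adjusted p = 0.107) and Igj means of 86.6 and 0.988 CPM (adjusted p = 0.863). No explanation of these levels was tested.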
